A study of Dictyostelium discoideum with 32 samples.

How the data were processed

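Poly-A RNA was sequenced from Dictyostelium discoideum cells of 4 strains at 4 times of development, with 2 replicates of each, which makes 32 libraries in 16 groups. Per the labels, cells grew axenically in HL5 medium, were washed, and developed on non-nutrient agar for 0, 1, 2 or 5 h. Libraries were barcoded and read as 50-base reads on an Illumina Genome Analyzer II. The submitters' processing notes name Bowtie 0.12.7. The genome build, the annotation, the counting rule, the strand of the libraries and the handling of reads with several matches were not given in the sources used here.

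For each library the authors deposited raw counts per gene and normalized values per gene for 12869 gene identifiers. The deposited counts were whole numbers, with library totals between 3265810 and 8450501. The deposited normalized values were of the RPKM type: each was the count divided by the library total and by 1 fixed factor per gene that followed gene length. This was worked out from the values of 9007 genes, whose log ratio of normalized value to count departed from a gene term plus a library term by at most 5.7e-12, against a tolerance of 1e-06. The fixed factor was 0.905 of the annotated gene length at the median, and its origin was not given in the sources used here. A gene names table for the dicty_2.7 assembly held 12736 of the identifiers, and 3604 of them had a symbol. Identifiers missing from that table held 0.57% of the counts, and 844 genes had 0 counts in every library.

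Differential expression was tested on the counts with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with 1 mean per group, TMM normalization and the default low-count filter of edgeR. That filter kept 10168 genes. The model had 16 residual degrees of freedom per gene, TMM factors between 0.84 and 1.19 and a common biological coefficient of variation of 0.173. A gene was called when its Benjamini-Hochberg adjusted p, computed over the 10168 genes of a comparison, was below 0.05. Levels are CPM as edgeR computes them, which are counts scaled by library total and TMM factor, given as mean and SD over the 2 replicates. Fold changes are fitted log2 values, the group named before the word "against" minus the other. There were 24 comparisons: gtaC-null against AX2, GFP-GtaC against gtaC-null, NLSex against GFP-GtaC and GFP-GtaC against AX2 at each time; 5 h against 0 h in each strain; 1 h and 2 h against 0 h in AX2; and the difference between strains in the change from 0 h to 5 h, for gtaC-null against AX2 and for NLSex against GFP-GtaC.

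Gene sets were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, and again with an estimated correlation and with fry. The sets were the genes called higher (AX2-induced) or lower (AX2-repressed) at 5 h than at 0 h in AX2 with at least a 2-fold change, and the genes called higher or lower by at least 2-fold in gtaC-null at 5 h. The AX2-induced and AX2-repressed sets were chosen on AX2 libraries alone and tested in the other strains. Their own medians in AX2 are therefore given for reference only. The sets from gtaC-null at 5 h were chosen on AX2 and gtaC-null libraries. They were tested only in NLSex against GFP-GtaC and give no independent evidence on AX2 or gtaC-null. In 9 comparisons, 29 lists of genes by function or family were also tested, which made 261 list tests adjusted together. The lists, the comparisons, the alternatives and the rule for naming genes were set before the data were examined.

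Named genes had a symbol, a call, at least a 2-fold change, a mean of at least 5 CPM and replicates that did not overlap between the groups. The rule took the 10 largest changes each way in gtaC-null against AX2, in NLSex against GFP-GtaC, in GFP-GtaC against gtaC-null at 5 h and in AX2 over 5 h, and the 4 largest each way elsewhere. It added up to 4 members of each list and a fixed group of developmental genes, whatever their values. Genes named outside this rule are marked as chosen after their values were seen.

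A fold change against a group with 0 counts is given as a lower bound, from a floor of 3 counts over the group. Against a group with 1 to 3 counts, the ratio is given with its 95% exact counting interval. Intervals and floors cover counting error only. Shares of genes have exact Clopper-Pearson 95% intervals. Overlaps of gene groups were tested with Fisher's exact test, two-sided, over the genes tested. That test takes genes as independent, which they are not, so its p-values overstate the evidence.

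The procedure was tested on simulated data built from the counts of the libraries. In gtaC-null against AX2 at 5 h, with 9824 genes, it recovered 58% of simulated 2-fold changes and 97% of 4-fold changes, and it called 12 unchanged genes. The changed genes were drawn only from genes above a minimum expected count, in a single simulated data set. These rates therefore do not cover low-count genes. With no gene changed, it called 0 genes in NLSex against GFP-GtaC at 5 h. A 2-fold change in a single gene was therefore often below what 2 replicates could detect.

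The alternatives were the size factors of DESeq2 in place of TMM, no low-count filter, the authors' normalized values with a pseudocount of 1 and limma, replicate number as a block over all strains or within each strain, the Wald test of DESeq2 1.42.0, a fit to the compared libraries alone, sets without a fold minimum, and 32 refits that each left out 1 library. The limma fit of the authors' values was used to see how far the split of calls between higher and lower held without TMM. It differs from the main fit in scaling, test and pseudocount, so its shifts cannot be credited to scaling alone. In that fit the median of all genes moved by more than 0.1 on the log2 scale in some comparisons. Those shifts are given with the results. Replicate numbers were not used to pair libraries, because the labels did not say what samples with the same number shared. The labels also did not say whether replicates came from separate cultures, so p-values measure only the spread between these samples. Batches were not given per library. No column or library was left out. Python 3.11.15 and matplotlib 3.10.9 drew the figures.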

Results

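The transcriptome of developing Dictyostelium was measured in wild-type AX2 cells, in cells lacking the GATA transcription factor gtaC (gtaC-null), and in gtaC-null cells that carried 1 of 2 forms of GtaC fused to green fluorescent protein. One form was GFP-GtaC. The other, NLSex-GFP-GtaC (NLSex), is read here from its name as carrying an added nuclear localization signal, which the labels do not spell out. Each strain was sampled at 0, 1, 2 and 5 h of starvation, with 2 replicate libraries per time, so n = 2 for every mean given. Library totals ran from 3265810 to 8450501 counts, with a median of 6334943, and between 10269 and 10941 genes were detected per library. The 10 most abundant genes held between 5.4% and 9.9% of the counts. Along the first principal component, with 54.9% of the variance, AX2 and GFP-GtaC libraries moved from the 0 h end to the 5 h end, while the gtaC-null libraries at 5 h lay at -23.5 and -21.9, between those of AX2 at 1 h (-36.8 and -25.9) and at 2 h (-17.3 and 15.8). The AX2 libraries at 5 h lay at 106.8 and 127.3.

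The amount of gtaC transcript (DDB_G0277589) differed widely between strains. AX2 held 37.9 ± 10 CPM (SD, n = 2) at 0 h, 68.9 ± 23 at 1 h, 78.8 ± 37 at 2 h and 194 ± 47 at 5 h, a rise of 2.36 on the log2 scale over 5 h (adjusted p = 5.5e-06). Counts remained in gtaC-null, at 20.2 ± 8.6, 25 ± 6.4, 27.7 ± 6.4 and 39.2 ± 4.9 CPM at the same times. The labels did not say which part of the gene was removed. The difference from AX2 was not called at 0 h (log2 -0.91, adjusted p = 0.29) and was called at 5 h (log2 -2.31, adjusted p = 1.2e-05). It was also called at 1 h (log2 -1.47, adjusted p = 0.014) and 2 h (log2 -1.50, adjusted p = 0.0082). The 1 h call was lost without AX2 replicate 1 (adjusted p = 0.18) or gtaC-null replicate 2 (0.11), and the 2 h call without AX2 replicate 2 (0.27) or gtaC-null replicate 2 (0.11). GFP-GtaC cells held 1640 ± 69, 1440 ± 520, 1470 ± 59 and 3570 ± 1100 CPM, which was 5.44 above AX2 on the log2 scale at 0 h (adjusted p = 5.3e-08) and 4.20 above it at 5 h (adjusted p = 2.3e-06). NLSex cells held 1150 ± 170, 2980 ± 1100, 3290 ± 310 and 3950 ± 470 CPM. NLSex and GFP-GtaC did not differ by the test at 0 h (log2 -0.50, adjusted p = 1), 1 h (1.05, adjusted p = 0.051) or 5 h (0.15, adjusted p = 0.79). At 2 h the difference was called (log2 1.17, adjusted p = 0.019), but not without GFP-GtaC replicate 1 (adjusted p = 0.12), GFP-GtaC replicate 2 (0.082) or NLSex replicate 2 (0.11).

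In starving AX2 cells, genes for cAMP signalling and some adhesion genes rose, and many genes expressed in growing cells fell. The adhesion gene tgrC1, which acts in kin recognition, rose from 0.586 ± 0.085 to 1210 ± 230 CPM between 0 h and 5 h (log2 10.97, adjusted p = 2.3e-11). Its partner tgrB1 rose from 3.61 ± 1.2 to 1340 ± 340 CPM, csaA from 10.1 ± 1.5 to 2050 ± 270 CPM, and the cAMP receptor gene carA-1 from 33 ± 0.12 to 1980 ± 13 CPM (log2 5.90, adjusted p = 1.5e-12). The adenylyl cyclase gene acaA rose from 1.65 ± 1.2 to 342 ± 8 CPM. Among the genes that fell, gp130 went from 542 ± 37 to 1.81 ± 1.2 CPM (log2 -8.25, adjusted p = 1e-14), pyr56 from 552 ± 90 to 2.01 CPM, and the cysteine protease gene cprD from 1270 ± 150 to 45 ± 2.5 CPM. Some fell within 1 h. The log2 change at 1 h was -6.05 for gp130 and -5.38 for acly, which went from 3450 ± 220 to 82.7 ± 13 CPM. Genes with 0 counts at 0 h included Ddaco, at least 354-fold higher at 5 h, and cmr, at least 307-fold higher.

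The test called 4337 genes at 1 h (2145 higher, 2192 lower), 5044 at 2 h (2599 higher, 2445 lower) and 7207 at 5 h (3885 higher, 3322 lower). All 76 ribosomal protein genes tested were lower at 5 h, with a median log2 of -1.73 (adjusted p = 3.8e-13; adjusted p = 0.6 with an estimated correlation). Of the 40 proteasome genes, 37 were higher and 0 lower (median 1.76, adjusted p = 1.7e-08; adjusted p = 0.6 with an estimated correlation), for example psmD14, which rose from 92.7 to 438 ± 52 CPM. The 24 genes for relay of the cAMP signal had 19 higher and 2 lower (20 and 2 adjusted over the list alone), with a median of 1.79 (adjusted p = 0.00014; adjusted p = 0.6 with an estimated correlation). The 16 adhesion genes went both ways, 9 higher and 5 lower (median 1.25), and the list did not pass (adjusted p = 0.19; adjusted p = 0.79 with an estimated correlation). Autophagy genes also rose, with 9 of 10 called (median 1.44, adjusted p = 0.0067; adjusted p = 0.41 with an estimated correlation), and atg8 went from 32 ± 3.9 to 211 ± 45 CPM. Of 39 nucleolar and ribosome-assembly genes, 33 were lower and 3 higher (median -4.50, adjusted p = 3.3e-09; adjusted p = 0.29 with an estimated correlation), with utp15 falling from 57.7 ± 1.6 to 1.09 CPM. Across all lists and comparisons, 102 of the 261 list tests passed with the preset correlation and 0 with an estimated one. In the limma fit of the authors' values the median of all genes at 5 h was 0.31, against 0.15 in the main fit. At 1 h it was 0.10 against 0.

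**Figure D1:**
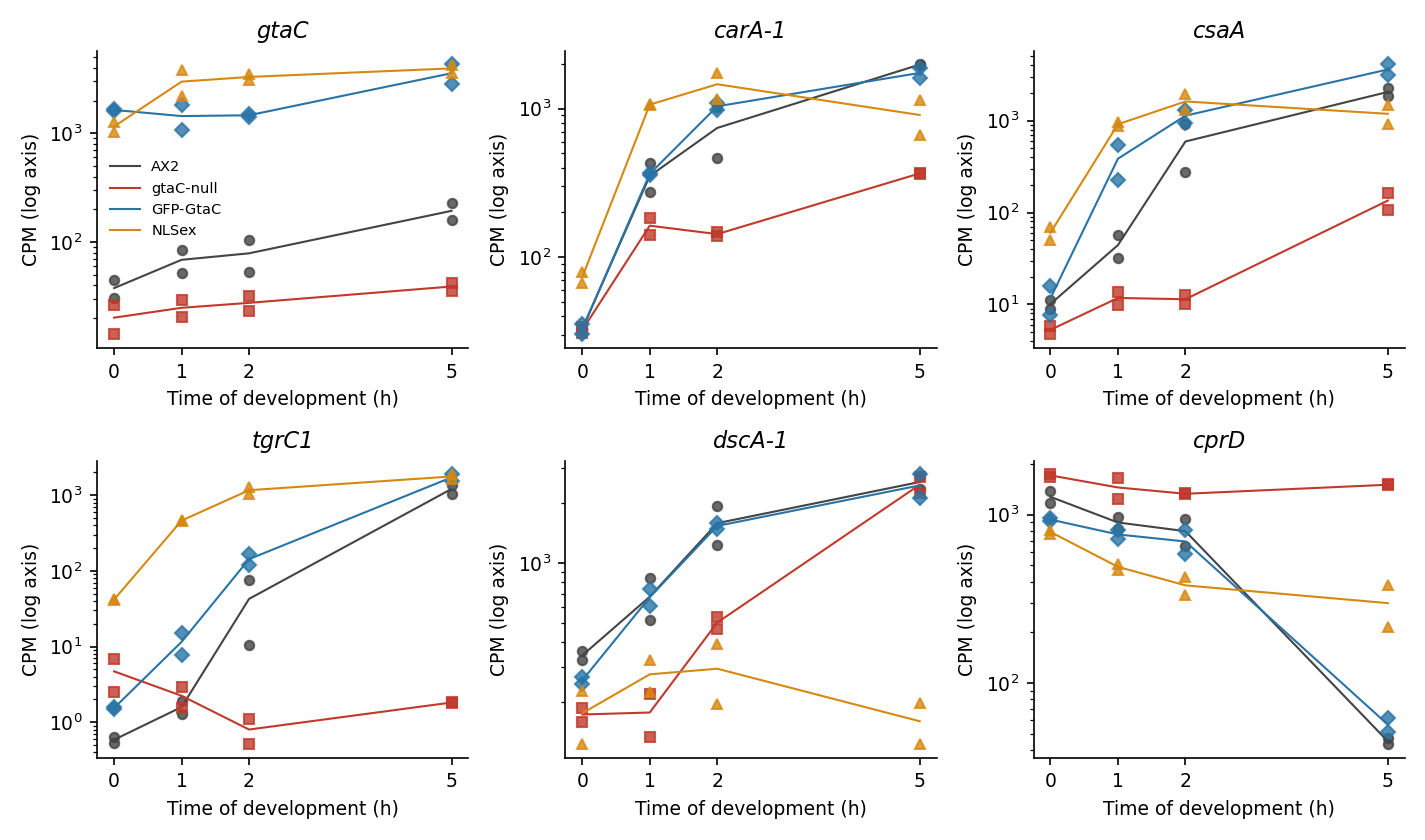
Level in CPM (log axis) against hours of development for gtaC, carA-1, csaA, tgrC1, dscA-1 and cprD in the 4 strains; points are single libraries and lines join group means. The tgrC1 panel shows AX2 at 1210 CPM and gtaC-null at 1.82 CPM at 5 h, and NLSex at 41.8 CPM already at 0 h.

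Before starvation, CBP2, a calcium-binding protein gene, was lower in gtaC-null (294 ± 69 against 1040 ± 43 CPM, log2 -1.83, adjusted p = 0.00038). Higher in gtaC-null were ponC4 (51.3 ± 13 against 12.3 ± 1.4 CPM, log2 2.05, adjusted p = 0.001) and adprh (276 ± 10 against 129 ± 0.35 CPM, log2 1.09, adjusted p = 0.001). The test called 131 genes at 0 h (87 higher, 44 lower). That count was lower in each refit without 1 of the 4 libraries, but such a refit leaves 1 library in a group and has less power. It was larger with other methods: 266 with replicate number as a block, 268 with DESeq2 and 511 with the compared libraries alone.

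At 1 h, gtaC-null cells held less of some genes of cAMP signalling and discoidin, and more heat-shock and prespore transcripts. Lower in gtaC-null were cafA (37 ± 2.3 against 269 ± 130 CPM, log2 -2.86, adjusted p = 2.2e-05), pdiA (59.1 ± 6.3 against 364 ± 190 CPM), acaA (4.19 ± 0.63 against 39.6 ± 34 CPM, log2 -3.25, adjusted p = 0.00032) and regA (71.2 ± 5.4 against 257 ± 100 CPM). Of 24 genes of cAMP relay and chemotaxis, 4 were lower and 1 higher. The other 19 were not called (adjusted p = 0.011 for the list; adjusted p = 0.63 with an estimated correlation). All 4 discoidin lectin genes tested were lower (median log2 -1.87, adjusted p = 1.1e-05; adjusted p = 0.29 with an estimated correlation), and dscA-1 stood at 177 ± 62 against 677 ± 230 CPM. Discoidin genes are near-identical, so reads could not be assigned to single members with certainty. Small heat-shock genes were higher, with hspG7 at 153 ± 15 against 8.7 ± 1.3 CPM (log2 4.13, adjusted p = 2.7e-05). All 12 tested members of the hspG family, chosen after its values were seen, were called higher. The list of heat-shock genes held only part of that family. Of 21 heat-shock genes, 6 were higher and 0 lower (9 and 0 adjusted over the list alone; adjusted p = 9.1e-05 for the list, and adjusted p = 0.3 with an estimated correlation). Of 40 aminoacyl-tRNA synthetase genes, 11 were higher and 0 lower (19 and 0 adjusted over the list alone), with a median of 0.44 (adjusted p = 2.1e-06; adjusted p = 0.25 with an estimated correlation), such as leuS at 451 ± 36 against 175 ± 49 CPM. Prespore genes were also higher, 7 of 14 called and 0 lower (8 and 0 adjusted over the list alone; adjusted p = 2.1e-05 for the list, and adjusted p = 0.32 with an estimated correlation). Among them, cotB stood at 13.4 ± 10 against 0.533 ± 0.46 CPM, and psvA, with 3 counts in AX2, was 60.9-fold higher over both replicates (95% interval 20.6 to 297). Its 2 gtaC-null libraries held 36.6 and 6.46 CPM, so most of that ratio came from replicate 1.

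At 1 h the test called 964 genes (579 higher, 385 lower). The count was 446 without AX2 replicate 1, 323 without AX2 replicate 2 and 525 without gtaC-null replicate 1. The limma fit of the authors' values, which moved the median of all genes to -0.10, turned the share called higher from 60.1% to 42.8%. The smaller differences of carA-1 and csaA at 1 h were also called, at log2 -1.11 (adjusted p = 0.016) and -1.92 (adjusted p = 0.015). Without AX2 replicate 2 their adjusted p was 0.24 and 0.18, and without gtaC-null replicate 1 it was 0.14 and 0.051. For csaA it was 0.1 without gtaC-null replicate 2.

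By 2 h the gap covered most of the cAMP-signalling and adhesion genes. In gtaC-null, csaA stood at 11.4 ± 1.9 CPM against 593 ± 450 in AX2 (log2 -5.70, adjusted p = 1.8e-07), tgrC1 at 0.801 ± 0.41 against 42.7 ± 45, and cad2 at 11.9 ± 0.39 against 385 ± 260 (log2 -5.01, adjusted p = 2.7e-08). The receptor gene carA-1 stood at 143 ± 6.8 against 742 ± 400 CPM, and the secreted phosphodiesterase gene pdsA at 428 ± 22 against 1300 ± 560. Higher in gtaC-null were comF-1 (107 ± 4.8 against 15.6 ± 11 CPM, log2 2.75, adjusted p = 4.7e-06) and grlG (75.6 ± 8.6 against 11.3 ± 8.8 CPM). The 2 AX2 libraries at 2 h differed more from each other in these genes than the gtaC-null libraries at 2 h did, as the SDs show. Of the 24 cAMP relay genes, 15 were lower and 1 higher (17 and 1 adjusted over the list alone), with a median of -0.83 (adjusted p = 4.2e-09; adjusted p = 0.31 with an estimated correlation). Of 16 adhesion genes, 9 were lower and 1 higher (median -1.36, adjusted p = 1e-06; adjusted p = 0.32 with an estimated correlation). The proteasome list had 19 lower and 0 higher (28 and 0 adjusted over the list alone; adjusted p = 1.2e-08 for the list, and adjusted p = 0.6 with an estimated correlation), and psmD9 stood at 20.3 ± 4.5 against 57 ± 8.6 CPM.

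The test called 1505 genes at 2 h (678 higher, 827 lower). The count was 355 without AX2 replicate 2, 679 without gtaC-null replicate 1 and 595 without gtaC-null replicate 2. The limma fit of the authors' values moved the median of all genes to 0.17 and the share called higher from 45% to 70.9%.

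At 5 h several adhesion and signalling genes that AX2 had induced stood at a few CPM or less in gtaC-null, and some genes that AX2 had shut off were still on. The prespore-inducing factor gene psiA stood at 0.608 ± 0.039 CPM against 687 ± 130 in AX2 (log2 -10.10, adjusted p = 4.7e-12), tgrC1 at 1.82 ± 0.053 against 1210 ± 230 (log2 -9.36, adjusted p = 1.6e-10), and the phosphodiesterase gene pde4 at 2.37 ± 0.068 against 178 ± 63. Genes with 0 counts in gtaC-null included rdiB, at least 412-fold lower than in AX2, and tgrO3, at least 80.6-fold lower. Part of the programme was reduced rather than absent: carA-1 stood at 367 ± 2.6 against 1980 ± 13 CPM (log2 -2.43, adjusted p = 3.3e-07), csaA at 135 ± 41 against 2050 ± 270, and acaA at 89.5 ± 18 against 342 ± 8. The differences for regA (log2 -0.15, adjusted p = 0.62) and dscA-1 (log2 -0.04, adjusted p = 0.92) did not pass the test, and dscA-1 had reached 2480 ± 330 CPM in gtaC-null and 2560 ± 270 in AX2. Higher in gtaC-null were cprD (1500 ± 4.2 against 45 ± 2.5 CPM, log2 5.06, adjusted p = 3.1e-12), the polyketide synthase gene stlA (222 ± 19 against 1.99 ± 1 CPM), and the size-sensing genes ctnA (2880 ± 520 against 143 ± 3.6 CPM) and smlA (507 ± 46 against 63.3 ± 9.7 CPM).

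The list of cAMP relay genes had 15 of 24 lower in gtaC-null at 5 h and 4 higher (median -0.86, adjusted p = 0.036; adjusted p = 0.66 with an estimated correlation), and the adhesion list 8 of 16 lower and 4 higher (median -1.72, adjusted p = 0.044; adjusted p = 0.65 with an estimated correlation). Lists for protein synthesis and breakdown differed as well. Of the 76 ribosomal protein genes, 65 were higher in gtaC-null and 0 lower (66 and 0 adjusted over the list alone), with a median of 0.99 (adjusted p = 3.3e-09; adjusted p = 0.62 with an estimated correlation). Of the 40 proteasome genes, 37 were lower and 0 higher (38 and 1 adjusted over the list alone), with a median of -1.38 (adjusted p = 3.4e-10; adjusted p = 0.6 with an estimated correlation), and psmA1 stood at 224 ± 19 against 676 ± 50 CPM. Of the 39 nucleolar genes, 30 were higher and 6 lower (median 2.58, adjusted p = 6.4e-07; adjusted p = 0.32 with an estimated correlation). The 9 vacuolar ATPase genes had 8 higher and 0 lower (median 1.03, adjusted p = 0.0029; adjusted p = 0.6 with an estimated correlation), including vatB at 1380 ± 74 against 322 ± 48 CPM. DNA replication genes had 22 of 32 higher and 2 lower (22 and 3 adjusted over the list alone; adjusted p = 0.0013 for the list, and adjusted p = 0.66 with an estimated correlation), and mcm3 stood at 19.3 ± 2.3 against 3.93 ± 2.7 CPM. Of the 28 tgr genes, 19 were lower and 3 higher, with a median of -5.76, or -4.82 with the 9 genes that had a group at 0 counts placed at their bound (adjusted p = 2.2e-06; adjusted p = 0.32 with an estimated correlation). Some tgr genes are close paralogs whose reads may be shared. The test called 6084 of 10168 genes at 5 h, or 59.8% (2940 higher, 3144 lower).

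gtaC-null cells did respond to starvation, but less than AX2 did. Between 0 h and 5 h they lost gp130 (log2 -7.84) and raised carA-1 (3.50), csaA (4.68), acaA (4.96) and dscA-1 (3.85), all called. They did not change tgrC1 (log2 -1.30, adjusted p = 0.15), tgrB1 (-0.47, adjusted p = 0.53) or cprD (-0.19, adjusted p = 0.55) by the test. The test called 4279 genes (2098 higher, 2181 lower). The limma fit of the authors' values moved the median of all genes to 0.26 and the share called higher from 49% to 68.3%. Of the 2904 AX2-induced genes, whose median change in AX2 was 2.02, 1326 were called higher in gtaC-null and 70 lower, with a median of 0.67 (0.64 with zero-count genes at their bound; adjusted p = 7.3e-31, and adjusted p = 0.0046 with an estimated correlation). Of the 2730 AX2-repressed genes, with a median of -2.33 in AX2, 1612 were called lower and 92 higher, with a median of -0.93 (adjusted p = 2.9e-46, and adjusted p = 0.0045 with an estimated correlation). The interaction test found 4402 genes whose change over 5 h differed between gtaC-null and AX2 (2237 above the AX2 change, 2165 below it). In the mean level of the AX2-induced genes relative to AX2 at 0 h, the gtaC-null libraries stood at 0.76 and 0.85 on the log2 scale at 1 h, close to AX2 (0.77 and 0.84), and at 0.89 and 0.90 at 5 h, against 2.31 and 2.52 in AX2.

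**Figure D2:**
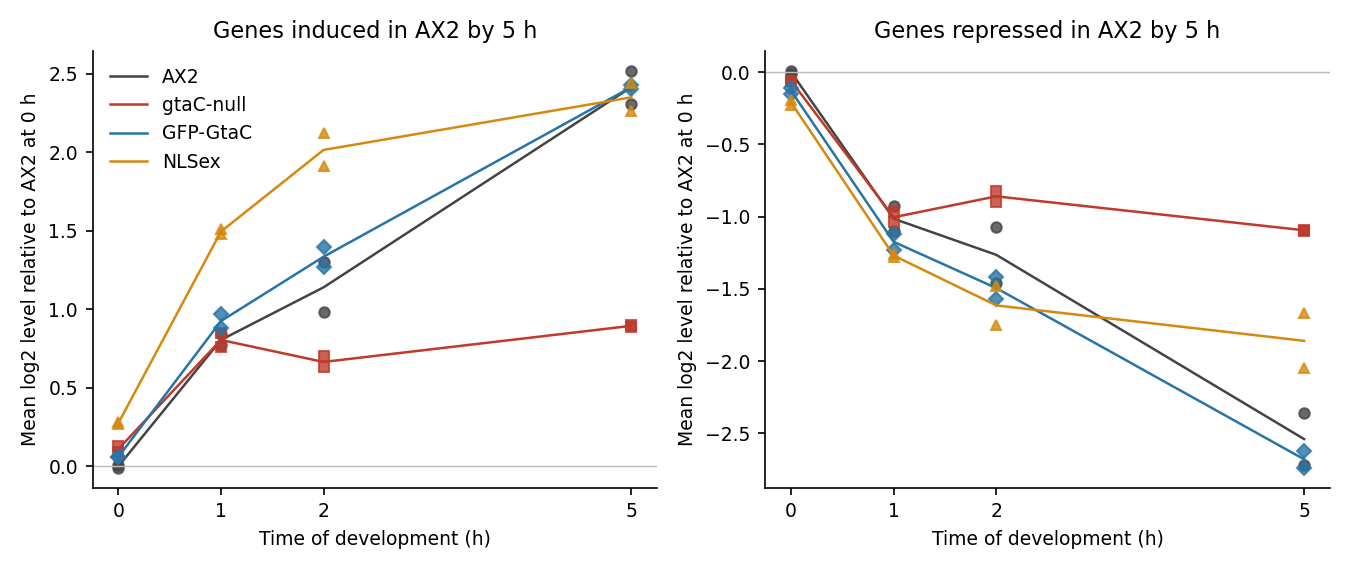
Mean log2 level of the AX2-induced genes and of the AX2-repressed genes, relative to AX2 at 0 h, against hours of development; points are libraries and lines join the means of each strain. At 5 h the induced genes stood at 0.89 and 0.90 in the gtaC-null libraries and at 2.26 to 2.52 in the libraries of the other strains.

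GFP-GtaC in gtaC-null cells was called opposite to the gtaC-null difference in most of the affected genes at 0, 2 and 5 h, and in 45.3% of them at 1 h. At 5 h, tgrC1 was 1720 ± 220 CPM in GFP-GtaC against 1.82 ± 0.053 in gtaC-null (log2 9.87, adjusted p = 6.9e-11), psiA was 594 ± 280 against 0.608 ± 0.039, and mrrA was 1600 ± 160 against 0.92 ± 0.32 (log2 10.75, adjusted p = 3.2e-11). Genes that gtaC-null had kept on were low, stlA at 1.26 ± 0.88 CPM against 222 ± 19 (log2 -7.41, adjusted p = 3.2e-10) and cprD at 56.5 ± 7.9 against 1500 ± 4.2. At 1 h, csaA was higher in GFP-GtaC than in gtaC-null (385 ± 230 against 11.8 ± 2.6 CPM, log2 5.04, adjusted p = 8.6e-07). The spore coat gene cotC was lower (0.78 ± 0.24 against 24.6 ± 19 CPM). Its gtaC-null libraries at 1 h held 37.9 and 11.2 CPM. Carry-over of cells from the multicellular stage into those libraries could not be told apart from expression. Already at 0 h the myosin gene mhcA stood at 1800 ± 630 CPM in GFP-GtaC against 158 ± 55 in gtaC-null (log2 3.51). Over 5 h, 2620 of the 2904 AX2-induced genes rose in GFP-GtaC and 8 fell, with a median of 1.93 (1.89 with zero-count genes at their bound; adjusted p = 9.1e-95, and adjusted p = 8.4e-05 with an estimated correlation). The AX2-repressed genes had a median of -2.50 (adjusted p = 3.4e-123, and adjusted p = 8.4e-05 with an estimated correlation).

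GFP-GtaC against gtaC-null had 1201 genes called at 0 h (661 higher, 540 lower), 1082 at 1 h (505 higher, 577 lower), 3206 at 2 h (1747 higher, 1459 lower) and 6549 at 5 h (3334 higher, 3215 lower). Without GFP-GtaC replicate 1, GFP-GtaC replicate 2, gtaC-null replicate 1 and gtaC-null replicate 2, in that order, the 0 h count was 778, 292, 722 and 424. The 1 h count was 691 and 685 without GFP-GtaC replicates 1 and 2 and 698 without gtaC-null replicate 1, and the 2 h count was 1510 without GFP-GtaC replicate 2 and 1595 without gtaC-null replicate 1. The limma fit of the authors' values changed the share called higher. It went from 55% to 42.9% at 0 h, from 54.5% to 25.1% at 2 h and from 50.9% to 39.7% at 5 h. The median of all genes moved to -0.28 at 2 h and -0.20 at 5 h. Of the genes that differed in gtaC-null, GFP-GtaC was called the opposite way in 96 of 131 at 0 h (73.3%, exact 95% interval 64.8 to 80.6), 437 of 964 at 1 h (45.3%, 42.2 to 48.5), 1121 of 1505 at 2 h (74.5%, 72.2 to 76.7) and 5199 of 6084 at 5 h (85.5%, 84.5 to 86.3). The 1 h share was 68.7% without AX2 1 h replicate 2, and 27.6% without GFP-GtaC 1 h replicate 1. Independent calls would have given 7.5, 52, 239.4 and 1960.5 such genes. Of the genes called in gtaC-null, 11, 216, 68 and 272 were called the same way in GFP-GtaC against AX2, which shares the AX2 libraries. The comparisons of GFP-GtaC with gtaC-null and of gtaC-null with AX2 share the gtaC-null libraries, which by itself favours opposite changes. Across genes, the correlation of the 2 sets of log2 fold changes was -0.615, -0.594, -0.779 and -0.931 at the 4 times, against means of -0.476, -0.454, -0.435 and -0.465 in 10 simulations without strain differences; genes are not independent replicates.

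GFP-GtaC was not identical to AX2. At 0 h, sigJ was higher (36.3 ± 0.41 against 4.32 ± 0.4 CPM, log2 3.06, adjusted p = 5.3e-06) and cxgS lower (5.64 ± 0.75 against 35.6 ± 4 CPM, log2 -2.65, adjusted p = 0.00028). At 1 h, GFP-GtaC cells were ahead in csaA (385 ± 230 against 44.2 ± 17 CPM, log2 3.12, adjusted p = 0.00066), and osbI was higher (43.3 ± 4.8 against 4.02 ± 1.2 CPM). At 5 h, elmoA was lower (3.93 ± 1.4 against 26.3 ± 6 CPM, log2 -2.73, adjusted p = 6e-05). The counts of called genes were 141 at 0 h (63 higher, 78 lower), 821 at 1 h (521 higher, 300 lower), 457 at 2 h (306 higher, 151 lower) and 1050 at 5 h (535 higher, 515 lower). These counts moved widely when 1 library was left out, which leaves 1 library in its group and lowers power. Without AX2 replicate 2 they were 58 at 0 h and 116 at 1 h, and without GFP-GtaC replicate 1 the 2 h count was 285. With the compared libraries alone they were 630, 362, 44 and 14. With replicate number as a block they were 249 at 0 h and 913 at 2 h, and with DESeq2 215 and 707. In the limma fit of the authors' values the share called higher changed as well. It went from 63.5% to 37.9% at 1 h, from 67% to 39.3% at 2 h and from 51% to 22.7% at 5 h. That fit moved the median of all genes to -0.12 at 1 h and -0.21 at 5 h.

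**Figure D3:**
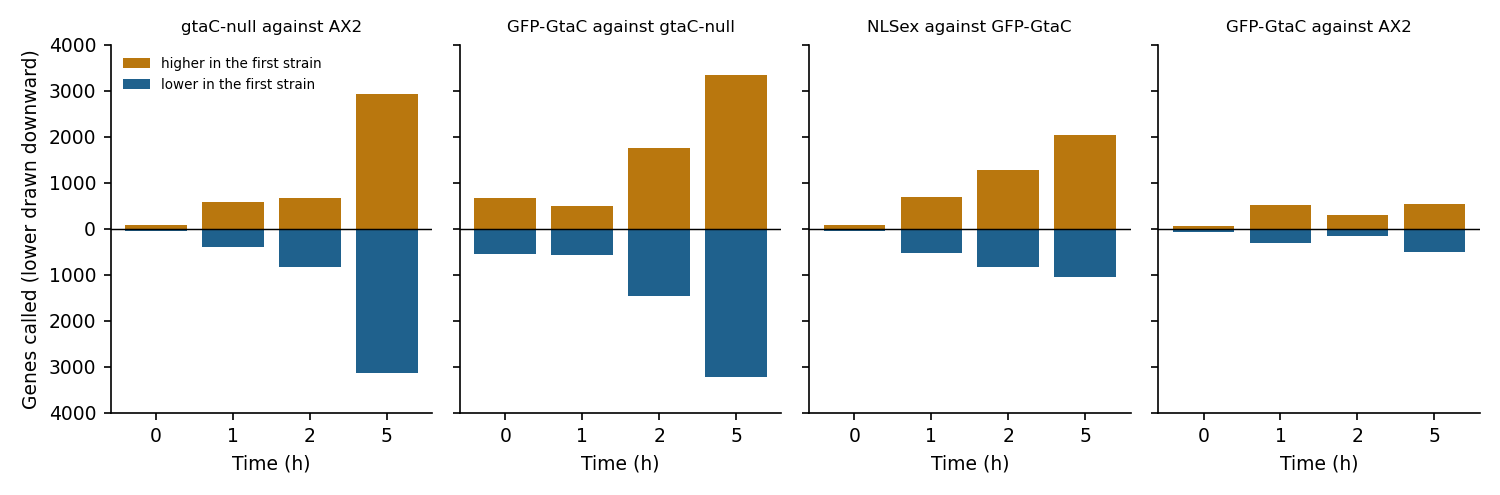
Number of genes called higher and lower (adjusted p below 0.05, 10168 genes tested) at 0, 1, 2 and 5 h for gtaC-null against AX2, GFP-GtaC against gtaC-null, NLSex against GFP-GtaC, and GFP-GtaC against AX2. The gtaC-null counts rose from 131 at 0 h to 6084 at 5 h, while the NLSex counts went from 115 to 3085.

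The comparison of NLSex with GFP-GtaC asks what a form of GtaC directed to the nucleus does to the timing of development. Before starvation, NLSex cells held more of some genes that AX2 induced in starvation. At 0 h, tgrC1 stood at 41.8 ± 0.25 CPM in NLSex against 1.54 ± 0.073 in GFP-GtaC (log2 4.74, adjusted p = 3e-04), mrrA at 78 ± 2.2 against 1.86 (log2 5.38, adjusted p = 3.5e-05), and cad2 at 78.9 ± 2.9 against 9.49 ± 0.74 (log2 3.05, adjusted p = 5.3e-05). The calcium-binding protein gene cbpA stood at 198 ± 7.1 against 13.5 ± 2.8 CPM. Lower in NLSex were ponB (5.7 ± 0.46 against 28.2 ± 2.9 CPM) and pdiA (47 ± 13 against 175 ± 8.3 CPM, log2 -1.89, adjusted p = 0.00036). Of the 76 genes called higher, 68 (89.5%) were AX2-induced. The share among all genes tested was 28.6% (Fisher's exact test with genes taken as independent, adjusted p = 1.4e-28 over 16 tests). The AX2-induced genes as a set had a median of 0.10 (camera, adjusted p = 2.6e-08, and adjusted p = 0.13 with an estimated correlation). The test called 115 genes (76 higher, 39 lower). The count was 42 without GFP-GtaC replicate 1, 46 without GFP-GtaC replicate 2, 68 without NLSex replicate 1 and 59 without NLSex replicate 2. The limma fit of the authors' values moved the median of all genes from -0.01 to 0.09 and the share called higher from 66.1% to 76.6%. Of the 28 tgr genes, 7 were higher and 0 lower (8 and 0 adjusted over the list alone), and the list passed with adjusted p = 1.8e-11, or adjusted p = 0.25 with an estimated correlation. The cAMP relay list had 0 of 24 called (2 higher and 0 lower adjusted over the list alone; median -0.03, adjusted p = 0.76) and the adhesion list 4 of 16 higher and 0 lower (4 and 1 adjusted over the list alone; median -0.24, adjusted p = 0.42). In 14 of the tgr genes a group had 0 counts, and with these at their bound the tgr median fell from 2.91 to 0.

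More genes were called higher in NLSex at 1 h and 2 h than at 0 h. At 1 h, tgrC1 stood at 462 ± 16 CPM in NLSex against 11.5 ± 5.4 in GFP-GtaC (log2 5.39, adjusted p = 7.8e-07), carA-1 at 1070 ± 8.6 against 364 ± 5.7 (log2 1.55, adjusted p = 0.00074) and acaA at 259 ± 14 against 55.5 ± 19. By 2 h tgrC1 had reached 1170 ± 170 CPM in NLSex, near its 5 h level in AX2, against 143 ± 33 in GFP-GtaC. The cysteine protease gene cprB stood at 948 ± 81 against 8.65 ± 4.9 CPM at 2 h (log2 6.83, adjusted p = 7.1e-10). The gene fnkB, with 0 counts in GFP-GtaC at 1 h, was at least 86.9-fold higher at that time. Other genes were lower. The early gene pdiA, already called lower at 0 h, was lower at 1 h (40.1 ± 1.7 against 275 ± 49 CPM, log2 -2.78, adjusted p = 6.6e-07). Discoidin dscA-1 was lower at 2 h (294 ± 140 against 1540 ± 84 CPM, log2 -2.39, adjusted p = 2.7e-05). The AX2-induced genes as a set were higher in NLSex by a median of 0.34 at 1 h (adjusted p = 1.3e-17) and 0.48 at 2 h (adjusted p = 3.9e-17), each with adjusted p = 0.025 with an estimated correlation. With zero-count genes at their bound the medians were 0.32 and 0.46. The genes called at least 2-fold lower in gtaC-null at 5 h had medians of 0.54 and 0.82 (adjusted p = 0.0071 and 0.0025 with an estimated correlation), or 0.48 and 0.78 at the bound.

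At these times the test called 1227 genes (698 higher, 529 lower) and 2127 genes (1288 higher, 839 lower). Among the genes called higher, 575 of 698 (82.4%) at 1 h and 970 of 1288 (75.3%) at 2 h were AX2-induced. The share among all genes tested was 28.6% (Fisher's exact test with genes taken as independent, adjusted p = 2e-207 and 1.3e-308). The tgr list had 11 higher and 1 lower at 1 h and 17 higher and 1 lower at 2 h (12 and 19 higher adjusted over the list alone; adjusted p = 5.3e-09 and 1.7e-12, and adjusted p = 0.29 and 0.25 with an estimated correlation). The cAMP relay list had 7 of 24 higher and 0 lower at 1 h (10 and 0 adjusted over the list alone; adjusted p = 0.011, and adjusted p = 0.63 with an estimated correlation), and 3 higher and 3 lower at 2 h (adjusted p = 0.99). The adhesion list had 4 of 16 higher and 1 lower at 1 h (5 and 3 adjusted over the list alone; adjusted p = 0.4), and 3 higher and 2 lower at 2 h (4 and 2 adjusted over the list alone; adjusted p = 0.75). Ribosomal protein genes were lower, 16 of 76 at 1 h and 33 at 2 h, with 0 higher (24 and 40 adjusted over the list alone), at medians of -0.51 and -0.72 (adjusted p = 8.3e-11 and 2.2e-14; adjusted p = 0.61 and 0.6 with an estimated correlation). Proteasome genes were higher at 2 h, 24 of 40 with 0 lower (29 and 0 adjusted over the list alone; median 0.63, adjusted p = 1.9e-06, and adjusted p = 0.62 with an estimated correlation). The 1 h count was 730, 711, 693 and 638 without GFP-GtaC replicates 1 and 2 and NLSex replicates 1 and 2, in that order, and the 2 h count was 1136 without GFP-GtaC replicate 1 and 1012 without NLSex replicate 2. The limma fit of the authors' values moved the median of all genes to 0.22 and 0.24. It moved the share called higher from 56.9% to 87.1% and from 60.6% to 83%.

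By 5 h NLSex cells expressed spore genes and some stalk genes, yet held more of many genes that AX2 had repressed. The spore coat gene cotC stood at 599 ± 120 CPM in NLSex against 2.07 ± 0.53 in GFP-GtaC (log2 8.15, adjusted p = 4.1e-10), pspD at 560 ± 25 against 8.48 ± 2.4 (log2 6.05, adjusted p = 8.4e-12), and the cellulose synthase gene dcsA at 471 ± 45 against 7.99. The prestalk gene ecmA stood at 17.8 ± 1.1 against 1.53 ± 0.83 CPM, and ampA at 1890 ± 75 against 203 ± 43. The gene cprD, which AX2 had repressed, stood at 298 ± 120 CPM against 56.5 ± 7.9 (log2 2.40, adjusted p = 1.8e-07). Also higher in NLSex was ctsD, at 1050 ± 430 against 129 ± 9.7 CPM. The discoidin gene dscA-1 stood at 160 ± 53 CPM against 2470 ± 480 (log2 -3.95, adjusted p = 6.9e-08), and pdsA at 632 ± 80 against 1810 ± 390. The adhesion genes tgrC1 (log2 0.04, adjusted p = 0.96) and tgrB1 (log2 -0.22, adjusted p = 0.74) no longer differed by the test. The lower levels of csaA (1190 ± 390 against 3600 ± 710 CPM, log2 -1.60, adjusted p = 0.0081) and carA-1 (906 ± 340 against 1740 ± 200 CPM, log2 -0.94, adjusted p = 0.015) were not called without NLSex replicate 1 (adjusted p = 0.12 and 0.25) or without GFP-GtaC replicate 1 (adjusted p = 0.069 and 0.11).

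Several lists differed at 5 h. Of the 14 prespore genes, 12 were higher in NLSex and 0 lower (median 4.38, adjusted p = 1.9e-09; adjusted p = 0.25 with an estimated correlation), and 8 of the 12 prestalk genes were higher and 0 lower (median 1.64, adjusted p = 0.0019; adjusted p = 0.25 with an estimated correlation). In AX2 over 5 h, 7 of these 12 prestalk genes had fallen and 4 had risen, so part of the list was also expressed in growing cells. Lysosomal enzyme genes had 16 of 27 higher and 2 lower (median 1.09, adjusted p = 0.0042; adjusted p = 0.41 with an estimated correlation), and nucleolar genes 18 of 39 higher and 0 lower (21 and 0 adjusted over the list alone; adjusted p = 2.9e-05, and adjusted p = 0.48 with an estimated correlation). The tgr list had 17 of 28 higher and 3 lower (18 and 3 adjusted over the list alone), with a median of 2.29 (adjusted p = 9.5e-05; adjusted p = 0.48 with an estimated correlation). The cAMP relay list had 11 lower and 2 higher (12 and 2 adjusted over the list alone; median -0.52, adjusted p = 0.0019, and adjusted p = 0.62 with an estimated correlation), and the adhesion list 7 lower and 1 higher (9 and 1 adjusted over the list alone; median -0.73, adjusted p = 0.01, and adjusted p = 0.62 with an estimated correlation). Ribosomal protein genes had 11 of 76 lower and 0 higher (0 and 0 adjusted over the list alone), with a median of -0.29 (adjusted p = 9.5e-06; adjusted p = 0.66 with an estimated correlation). All 4 discoidin genes were lower (median -4.12, adjusted p = 2e-06; adjusted p = 0.25 with an estimated correlation). The proteasome list, higher at 2 h, had 24 lower and 0 higher at 5 h (32 and 0 adjusted over the list alone; median -0.58, adjusted p = 7.4e-10, and adjusted p = 0.6 with an estimated correlation). Of the 2046 genes called higher, 1128 (55.1%) were AX2-repressed. The share among all genes tested was 26.8% (Fisher's exact test with genes taken as independent, adjusted p = 1.8e-207). Genes higher in gtaC-null at 5 h were higher in NLSex too, with a median of 1.10 (adjusted p = 5.6e-32; adjusted p = 0.022 with an estimated correlation). The median of the AX2-induced genes was -0.22 at 5 h (adjusted p = 8.4e-09; adjusted p = 0.12 with an estimated correlation), and -0.121 without NLSex replicate 1.

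The test called 3085 genes at 5 h (2046 higher, 1039 lower), 1710 without GFP-GtaC replicate 1 and 1590 without NLSex replicate 1. The limma fit of the authors' values moved the median of all genes from 0.08 to 0.21 and the share called higher from 66.3% to 80.9%. Over its own 5 h, NLSex raised 2425 of the 2904 AX2-induced genes and lowered 17 (median 1.66, adjusted p = 2.8e-70; adjusted p = 0.00018 with an estimated correlation). It lowered 2179 of the 2730 AX2-repressed genes and raised 50, with a median of -1.63 (adjusted p = 9.8e-87; adjusted p = 0.00032 with an estimated correlation), against -2.50 in GFP-GtaC. The level of dscA-1 did not change by the test in NLSex (log2 -0.13, adjusted p = 0.74). The interaction test found 1550 genes whose change over 5 h differed between NLSex and GFP-GtaC (1120 above the GFP-GtaC change, 430 below it). The count was 1006 without GFP-GtaC 0 h replicate 1, 987 without GFP-GtaC 5 h replicate 1 and 849 without NLSex 5 h replicate 1.

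**Figure D4:**
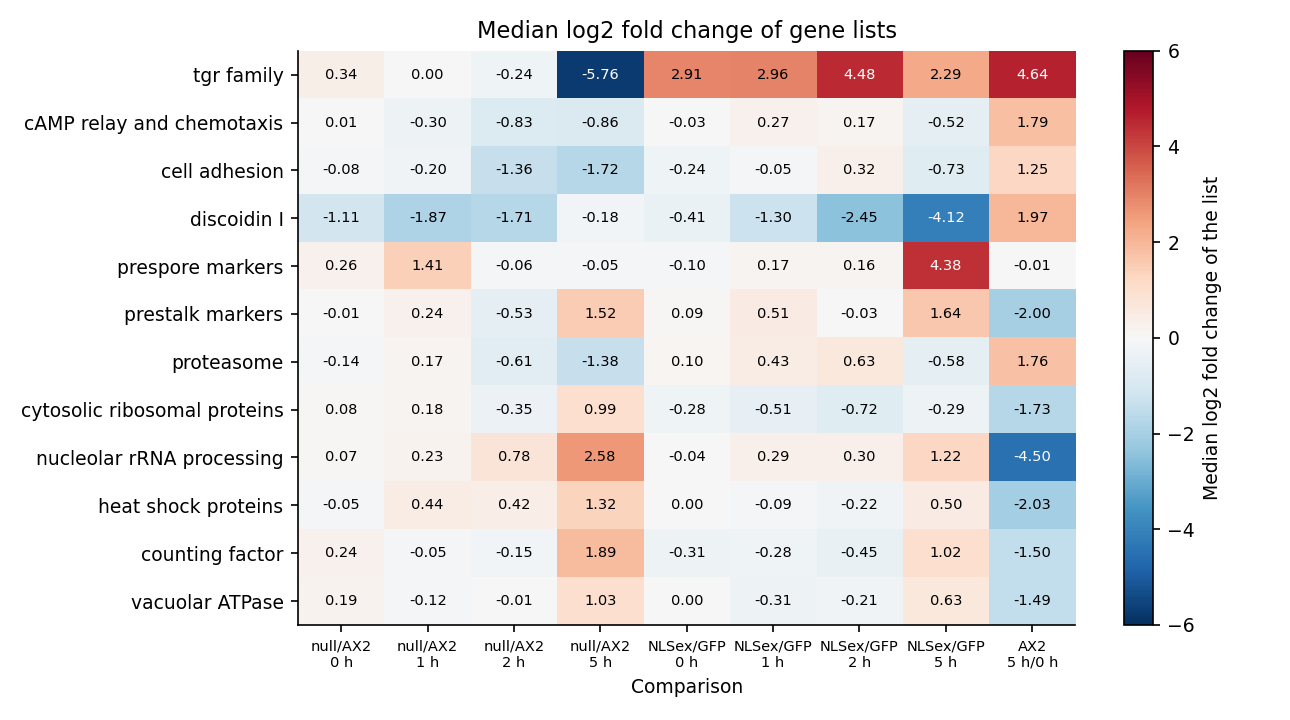
Heat map of the fitted median log2 fold change of 12 gene lists (vertical) in 9 comparisons (horizontal), including genes with 0 counts in a group at their fitted value. The prespore list reached 4.38 in NLSex against GFP-GtaC at 5 h, and the proteasome list went from 0.63 at 2 h to -0.58 at 5 h. In that comparison, the limma fit of the authors' values moved the median of all genes to 0.24 and 0.21.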

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

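In the weighing of 3 patterns in this part, the tests for the prespore genes, for mixed cells in NLSex and for progress of the AX2 replicates were chosen after the result was seen. The test of library depth was set before, except for the thinning of a library against itself, which was added after.

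The change in gene expression over 5 h differed between gtaC-null and AX2 in 4402 genes, by a test of the difference itself (edgeR interaction term). No list was tested for this difference, so it is given for single genes. The log2 change of tgrC1 was lower in gtaC-null by -12.27 (-1.30 against 10.97, adjusted p = 1.5e-08), that of tgrB1 by -8.98 (-0.47 against 8.51, adjusted p = 2.1e-08) and that of csaA by -2.98 (4.68 against 7.66, adjusted p = 0.0019). Also lower in gtaC-null were the changes of pde4, by -5.99 (adjusted p = 0.00023), gpaB by -2.62 (adjusted p = 5.5e-06) and carA-1 by -2.40 (adjusted p = 8.5e-05). The calcium-dependent adhesion gene cadA fell further, with a difference of -2.43 (-3.64 against -1.21, adjusted p = 4.1e-06). In the other direction, cprD differed by 4.64 (-0.19 against -4.82, adjusted p = 3.5e-09) and mybB by 1.62 (1.69 against 0.06, adjusted p = 0.0012).

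Differences in 4 more genes lost their call in some refits without 1 library. Such a refit leaves 1 library in a group, which lowers power. The difference for acaA was -2.66 (4.96 against 7.62, adjusted p = 0.016), with adjusted p = 0.086 without AX2 0 h replicate 2 and 0.092 without gtaC-null 0 h replicate 1. For gtaC itself it was -1.40 (adjusted p = 0.033), with adjusted p = 0.14 without AX2 0 h replicate 1, 0.13 without AX2 5 h replicate 2, 0.25 without gtaC-null 0 h replicate 1 and 0.099 without gtaC-null 5 h replicate 2. For pdsA it was -1.01 (2.42 against 3.43, adjusted p = 0.021), with adjusted p = 0.061 and 0.066 without AX2 0 h replicates 1 and 2, 0.087 without AX2 5 h replicate 1, 0.065 without gtaC-null 0 h replicate 2 and 0.068 without gtaC-null 5 h replicate 1. For cprE it was 1.23 (-0.92 against -2.16, adjusted p = 0.034). Its adjusted p was 0.062 and 0.054 without AX2 0 h replicates 1 and 2, 0.16 without AX2 5 h replicate 2, 0.14 without gtaC-null 0 h replicate 1, and 0.079 and 0.055 without gtaC-null 5 h replicates 1 and 2.

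Between NLSex and GFP-GtaC the change over 5 h differed in 1550 genes by the same test, 1006 without GFP-GtaC 0 h replicate 1, 987 without GFP-GtaC 5 h replicate 1 and 849 without NLSex 5 h replicate 1. Discoidin dscA-1 rose in GFP-GtaC and not in NLSex, a difference of -3.40 (-0.13 against 3.27, adjusted p = 7.7e-05). Smaller rises in NLSex were those of tgrC1 by -4.70 (5.41 against 10.10, adjusted p = 0.00055) and tgrB1 by -3.24 (4.90 against 8.14, adjusted p = 0.0019), both called higher in NLSex at 0 h and not called at 5 h. That of csaA, called higher at 0 h and lower at 5 h, was smaller by -3.96 (4.30 against 8.26, adjusted p = 0.00032). The rises of carA-1 (-2.10, adjusted p = 0.0012) and pdsA (-1.46, adjusted p = 0.0051) were also smaller in NLSex. The gene cprD fell less (2.64, -1.40 against -4.05, adjusted p = 1.9e-05). For gpaB the difference was -1.47 (adjusted p = 0.0061), with adjusted p = 0.055 without NLSex 5 h replicate 1. For cprE it was 1.78 (-0.49 against -2.27, adjusted p = 0.01), with adjusted p = 0.055 without GFP-GtaC 0 h replicate 1, 0.067 without GFP-GtaC 5 h replicate 2, 0.065 without NLSex 0 h replicate 1 and 0.18 without NLSex 5 h replicate 1. For acaA it was -2.38 (4.62 against 7, adjusted p = 0.028), with adjusted p = 0.08 and 0.073 without GFP-GtaC 0 h replicates 1 and 2, 0.069 without GFP-GtaC 5 h replicate 1, 0.095 without NLSex 0 h replicate 2 and 0.13 without NLSex 5 h replicate 1.

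Of 14 prespore genes, 7 were called higher in gtaC-null than in AX2 at 1 h, some with more in replicate 1 than in replicate 2 and little at 2 h: cotC stood at 37.9 and 11.2 CPM and cotB at 20.8 and 5.94 CPM, and cotC was at 1.09 and 0.637 CPM at 2 h. Other members of the list were not low at 2 h, such as cotD at 72.1 and 28.9 CPM at 1 h and 76.4 and 59.8 CPM at 2 h. Reads from the NLSex libraries at 5 h, where these genes are abundant, were argued against: across 75 genes abundant there and near 0 in gtaC-null, the upper quartile of observed over expected level was at most 0.17, and gtaC itself stood at 29.5 CPM where 409.7 would be expected. Carry-over of cells from the multicellular stage could not be told apart from expression within gtaC-null cells, which was not tested. The prespore and prestalk lists differed in mean log2 difference (2.25 and 0.14, two-sided permutation p = 0.012 with genes taken as independent). Their medians were 1.41 and 0.24. However, 0 prestalk genes were both low at baseline and abundant in some library, so the comparison could not exclude such cells.

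NLSex at 5 h held more of many genes that GFP-GtaC had shut off, though their level had mostly fallen. The share kept was the excess over the GFP-GtaC 5 h level, relative to the fall in GFP-GtaC from 0 h. Over the 394 genes that fell at least 8-fold in GFP-GtaC, the median share was 9% (quartiles 3.9% and 15.7%). If undeveloped cells had been mixed into cells at the GFP-GtaC 5 h state, these genes would keep a common share. Instead, 47.7% of the 394 genes lay outside a factor of 2 of the median share, against at most 10.2% in 100 simulated mixtures. Cells at the 2 h state gave 30.7% of the genes outside that factor, against at most 7.9% in simulated mixtures. Neither mixture with cells at the GFP-GtaC 5 h state was therefore likely as the whole cause. The simulated mixtures used GFP-GtaC levels for both parts. They could not exclude a mixture of NLSex cells whose own levels differ from those of GFP-GtaC. A mixture of several states was not tested. A response within the cells to the NLSex form of GtaC, which the design names, stayed open as a hypothesis, as did slower shut-off in NLSex.

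The AX2 replicates at 2 h stood further apart than most: csaA had an SD of 450 around 593 CPM. The difference between them followed the change that GFP-GtaC made from 1 h to 5 h, with a correlation across genes of 0.51, against -0.10 to 0.42 in the other groups tested; genes are not independent replicates. Library depth (7459669 and 5578618 counts over the genes tested) was argued against, since the correlation was 0.52 after thinning removed 25.2% of the counts of replicate 1. Replicate 1 thinned in this way and set against itself gave a correlation of 0.02. A difference in developmental progress between the plates or cultures is a candidate explanation, with replicate 2 ahead. The correlation was also positive in AX2 at 5 h (0.30), GFP-GtaC at 2 h (0.26) and NLSex at 2 h and 5 h (0.42 each). In the other groups tested it lay between -0.10 (gtaC-null at 0 h) and 0.19 (AX2 at 1 h). Replicate 2 may thus have been ahead in some other groups too.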

How the results depend on the processing

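Between the 2 replicates of a group, a common biological coefficient of variation of 0.173 and totals as low as 3265810 counts limited the detection of 2-fold changes, and a lone library left by a refit was assumed to vary like the other groups. The counts of called genes at 5 h in gtaC-null against AX2 and in GFP-GtaC against gtaC-null stayed within 1.5 times under each alternative run. So did the counts over time in each strain. The median changes over time kept their direction and also stayed within 1.5 times. The share called higher moved with the authors' values. It went from 49% to 68.3% in gtaC-null over 5 h, and from 50.9% to 39.7% in GFP-GtaC against gtaC-null at 5 h. With replicate number as a block, the counts at 0 h were 266 (gtaC-null against AX2) and 249 (GFP-GtaC against AX2), and 913 at 2 h in the latter. With the Wald test of DESeq2 they were 268, 215 and 707. With the compared libraries alone, which leaves fewer residual degrees of freedom, gtaC-null against AX2 gave 511, 608 and 789 genes at 0, 1 and 2 h, and GFP-GtaC against gtaC-null 1947 and 420 at 0 and 1 h. NLSex against GFP-GtaC gave 208 and 748 at 0 and 1 h, and GFP-GtaC against AX2 630, 362, 44 and 14 at the 4 times. The cause of these shifts was not tested.

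With an estimated correlation and with fry, 7 set medians of NLSex against GFP-GtaC kept their direction but no longer passed: AX2-induced genes at 0 h (0.097) and 5 h (-0.22), genes lower in gtaC-null at 0 h (0.109) and 5 h (-0.249), and genes higher in gtaC-null at 0 h (-0.065), 1 h (-0.168) and 2 h (-0.259). With the authors' normalized values the last set reversed at 0 h (0.043) and 1 h (0.056); the cause was not tested. Of the 102 list calls, 0 held with an estimated correlation (camera), while members were called singly by edgeR. With fry some lists passed and others did not. In gtaC-null against AX2 at 1 h, fry gave adjusted p = 0.001 for prespore genes and 9.8e-05 for discoidin genes. For cAMP relay genes at 1 h it gave 0.1. At 2 h fry gave 8.2e-05 for cAMP relay, 0.013 for proteasome and 0.14 for ribosomal protein genes. List counts and overlaps were not refitted without single libraries. Pairs of groups had correlations of replicate differences from -0.27 to 0.41, with a median of 0.08 over 120 pairs and 51 above 0.1. Among times within a strain the median was 0.13, with 17 of 24 pairs above 0.1, so same-numbered replicates of a strain may share something; the labels do not say what, and they were not taken as pairs. The block within each strain ended 0 of 237 called values of single genes (edgeR).

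A refit without 1 library left 1 library in a group, so a lost call or a lower count may reflect lost power. Leaving out 1 library at a time gave these lowest and highest counts at 0, 1, 2 and 5 h. They were 31 to 56, 323 to 856, 355 to 2136 and 4783 to 6038 for gtaC-null against AX2. They were 292 to 778, 685 to 985, 1510 to 2494 and 5626 to 5893 for GFP-GtaC against gtaC-null. They were 42 to 68, 638 to 730, 1012 to 1836 and 1590 to 2592 for NLSex against GFP-GtaC. They were 49 to 98, 84 to 765, 30 to 674 and 195 to 1468 for GFP-GtaC against AX2. The NLSex interaction count ran from 849 to 1606. The share of gtaC-null differences called the opposite way in GFP-GtaC ran from 52.6% to 92.2% at 0 h, 27.6% to 68.7% at 1 h, 54% to 88.5% at 2 h and 77.1% to 87.6% at 5 h. Genes higher in gtaC-null ran from -0.07 to 0.016 in NLSex at 0 h, reversed without GFP-GtaC replicate 1 (0.016) and NLSex replicate 1 (0.011); the cause was not tested.

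Of 1075 called values of single genes, 340 lost the call when some library was left out, 98 of 1055 with the compared libraries alone, 93 with the authors' values, 18 of 1068 with DESeq2, 14 without the low-count filter, 6 with DESeq2 size factors and 1 with the block. None of these changed sign.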

Other observations

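A family of 12 small heat-shock genes, hspG, was higher in gtaC-null and in GFP-GtaC than in AX2 early in development. In gtaC-null against AX2, 0 of the 12 were called at 0 h, 12 were higher at 1 h (median log2 3.93), 11 at 2 h (2.02) and 4 at 5 h (0.77), with 0 lower. GFP-GtaC against AX2 had 9 higher at 0 h (median 2.31), 9 at 1 h (2.22), 5 at 2 h (1.65) and 0 at 5 h. For hspG7 the level at 0 h was 12.8 ± 5.2 CPM in AX2, 15.4 ± 9.3 in gtaC-null, 60.5 ± 3.4 in GFP-GtaC and 121 ± 5.1 in NLSex (SD, n = 2). At 1 h it was 8.7 ± 1.3, 153 ± 15, 56.4 ± 38 and 60.6 ± 12 CPM in the same order. NLSex was not compared with AX2 by a test. The family was singled out after its values were seen, its members are close paralogs whose reads could not be assigned with certainty, and no explanation was tested.

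A test chosen after the result was seen asked whether genes respond in a graded way to the amount of gtaC before starvation. In that case, gtaC-null and GFP-GtaC, with 20.2 and 1640 CPM of gtaC, would lie on opposite sides of AX2. The shared AX2 libraries push the covariance of the 2 sets of fold changes upward, to between 0.054 and 0.063 in 20 simulations with no effect. The observed covariance was 0.053, just below the lowest simulated value. The correlation was 0.115, against a mean of 0.477 in the simulations, but a correlation also falls when either strain differs from AX2 for unrelated reasons, so it did not decide between them. Of the genes called in both comparisons, 14 went opposite ways and 11 the same way. The margin in covariance was too small to set a graded response apart from no response. The simulations also drew each gene at its mean over all 32 libraries with 1 dispersion, not at its 0 h level and spread. The AX2 replicates at 0 h stood closest together of the 16 groups (SD of the log2 difference 0.37). The simulated range may therefore not hold at 0 h, and the test could not decide the question.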
